A study of Danio rerio with 12 samples.

How the data were processed

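Gene expression was measured on 12 Agilent 1-colour arrays, each hybridised with Cy3-labelled RNA from a pool of whole zebrafish embryos of the wild-type AB strain. Per the labels' protocols, embryos were injected at the 1-4 cell stage with 0.25 to 1.0 pmol of each morpholino and kept at 28.5 °C, RNA came from pools of 18 to 35 embryos, and 100 ng of it was amplified and labelled. Morpholinos are antisense oligonucleotides that block translation or splicing of a chosen transcript. The 4 groups of 3 arrays were control morpholino at 6 h, control morpholino at 24 h, PCSK7 plus p53 morpholinos at 6 h and PCSK7 plus p53 morpholinos at 24 h, all in hours post fertilization. The p53 morpholino was given only together with the PCSK7 morpholino, so every comparison of morpholinos holds the effect of both. Groups and replicate numbers were taken from the labels. Nothing in the labels says that replicates came from separate clutches or injection days, so p-values measure the spread between these pools, part of which may be technical.

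The deposited scanner files give each spot's intensity on a linear scale, background-subtracted and spatially detrended by Agilent Feature Extraction, per the file headers. Version 10.7.1 is named in the submitters' processing notes, and the file headers name builds 10.7.1.1 and 10.7.3.1. The authors' deposited table of processed values holds 19838 probes as intensity on a linear scale. Each of its columns ranked the probes as the scanner signal of the same array did (lowest rank correlation 1.0, highest with another array 0.9967). Every column had the median 172.1, and sorted columns differed by at most 8.58, as quantile normalization gives. The values were on a linear scale, were not centred per gene and had no direction of their own, but how they were normalized and why these probes were chosen is not given in the sources used here. This table was used only as an alternative. It has 0 columns without a sample.

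Spots of the same probe were averaged after flagged spots were left out, which left 76 of the 43603 non-control probes without a value on some array. The main values were log2 of the processed signal minus the array's 75th percentile over non-control probes. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which held for 36686 probes. Probes were named through the RefSeq accessions in the files and a RefSeq gene table of assembly GRCz12tu. Accessions were on 33678 probes, and 26854 probes received a name, for 14016 genes. The file headers name 2 annotation releases, and 15 probes that these gave to different genes stayed unnamed, as did all others of the 16749 unnamed probes. No coordinates are given because the array design and the table use different genome builds. None of the named probes (0) was assigned to pcsk7, whose level is not analysed here. The kept probes covered 12849 genes, 7375 of them with 2 or more kept probes. A gene is represented by its probe with the highest mean signal over all 12 arrays. Disagreement between probes in direction or call is stated where a gene is named by its fitted change at 6 h or 24 h. Probes that agree can still differ in size.

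The tests were limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with 1 mean per group over all 12 arrays, 8 residual degrees of freedom and 2.08 prior degrees of freedom. The median residual SD was 0.14 on the log2 scale. Benjamini-Hochberg adjustment ran over all kept probes, and a call is an adjusted p under 0.05. The 5 comparisons were PCSK7 plus p53 against control morpholino at 6 h and at 24 h, the difference between these effects, and 24 h against 6 h within each morpholino. A gene well above background on all arrays of 1 group and on none of the other has only a bound there. It is given as "at least N-fold", the bright group's mean over the dim group's mean of, per array, the lowest signal of any probe well above background or the probe's own signal if higher. Genes above background on some arrays of the dim group have their bound made in the same way.

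At 6 h many kept probes were above background only at 24 h, so counts for genes well above background on all arrays of a group of the comparison are given beside the planned ones, a choice made after seeing the data.

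The 34 gene lists were fixed before the data were examined. They were proprotein convertases, TGF-beta pathway, TGF-beta responsive genes, Nodal and mesendoderm genes, BMP and dorsoventral genes, maternal transcripts, p53 pathway, apoptosis, interferon and innate immunity, neural progenitors, neurons, brain regions, eye, lens, inner ear, somites and skeletal muscle, heart, blood, endothelium, notochord and floor plate, extracellular matrix and proteases, hatching gland, neural crest and pigment, endoderm and liver, yolk lipid transport, epidermis and enveloping layer, cell cycle, ER stress and chaperones, heat shock proteins, Hox genes, Wnt, FGF, hedgehog and retinoic acid, circadian clock, ribosomal proteins, and mitochondrial respiration. Each was tested against all other named genes with limma's camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists, and again with a correlation estimated for each list. No list passed at any of the 3 comparisons with the estimated correlation (0 of 34 each). Counts of members that rose or fell use the adjustment over all probes, and a second count uses the adjustment over the list alone.

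Genes were named by a rule set before the data were examined. It took the genes that the labels or the title name with every probe. For each comparison of morpholinos it took the 10 largest rises and the 10 largest falls among genes with a call, well above background on all 6 arrays and with no overlap between the groups. It further took up to 5 genes each way by their bound, up to 4 members of each list with the smallest adjusted p, and the 5 largest each way for the other comparisons. Among the list members that the rule allows, those named in the text were picked after their values were seen, and a few genes that the rule takes are not reported here. A stage position was computed per array as the mean, over genes that changed at least 4-fold between control 6 h and control 24 h, of the distance covered from the control 6 h mean (0) to the control 24 h mean (1), leaving a control array out of its own reference. It was compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 arrays is 0.1.

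Probe calls, the list test at each time and the stage position were tested on simulated data, the calls with 200 changed probes among 36686. At 6 h, 77 of 100 probes changed 2-fold and 46 of 100 changed 1.5-fold were recovered with 4 false calls. At 24 h these were 71, 51 and 8, and for the difference 57, 21 and 2. On 12849 genes the list test recovered the 1 changed list at 6 h and at 24 h. It gave 0 false calls among the other lists. Simulated genes varied independently, so false calls from correlated genes were not tested. No slide or session effect was simulated. The 200 changed probes were far fewer than the 21885 calls at 6 h, so the recovery and false-call counts do not carry over to the real calls. Stage positions simulated at 0.1 and 0.9 came back as 0.1 and 0.898 over 5017 genes.

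Arrays differed in brightness. The 75th percentile of the signal was 401 to 1080 (401 to 509 in control and 630 to 726 in morpholino embryos at 6 h), 67.6 to 82.3% of spots were well above background, 0 spots were saturated, and the median coefficient of variation of replicate spots was 4.81 to 7.64%. Replicates correlated at 0.992 to 0.994 over 12 pairs, with 0 probes of identical signal in any pair. The number of arrays limits the precision. Control arrays lay on slides 1 to 3, each with an array of both times, and were scanned in session 1. Morpholino arrays lay on slide 4 (6 h) and slide 5 (24 h) and were scanned in session 2. Slide and scan session therefore cannot be told apart from the morpholino group in either comparison of morpholinos. The 10 spike-in probes had a median log2 signal -4.00 lower in session 2 (range -4.42 to -0.43), so the amount of spike-in, the labelling or the scan differed between sessions. The slope of the spike-in response was 0.926 to 0.960 in session 1 and 1.00 to 1.06 in session 2.

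Alternatives planned beforehand were normexp background correction with an offset of 50, quantile and median scaling, the 75th percentile over probes detected on all 12 arrays, other filters on dim probes, a floor on low values, the replicate number as a block, slide as a random or fixed block, an intensity trend in eBayes, fits of the compared groups alone, the authors' table, other list tests, and leaving out each replicate. The planned normexp used the median spot signal because the mean spot signal is not in the files. It was upset by 4, 6 and 10 spots with very high local background on 3 arrays, so a version with local background capped at 10 times the array's median was added. Cyclic loess and a filter on the compared groups alone were also added, all after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.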

Results

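The series set out to compare zebrafish embryos injected with morpholinos against PCSK7, a proprotein convertase that cleaves precursor proteins in the secretory pathway, with embryos given a control morpholino, and its title also names TGF-beta 1a. The p53 morpholino that came with it is commonly used to limit cell death caused by injection. Each of the 4 groups had 3 arrays, with 6 h (early gastrula) and 24 h (end of segmentation) as the times. The targeted transcript, pcsk7, had 0 named probes and is not analysed here. Values below are log2 changes with the standard error of limma's fit (n = 3 arrays per group, 12 arrays in the fit). Control and morpholino arrays lay on different slides and scan sessions, so slide and session cannot be told apart from the morpholino group wherever these groups are compared.

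The gene tgfb1a, which the title names and which encodes the ligand TGF-beta 1a, fell at 6 h on both of its probes, by 3.88 (SE 0.21, adjusted p = 4.77e-07) and by 3.11 (SE 0.32, adjusted p = 2.16e-05). Each probe was well above background on all 3 control arrays and on 1 of the 3 morpholino arrays. These fitted changes therefore rest in part on signal at background. For the second probe the bound was at least 6.14-fold lower. For the first it was 14.7-fold, which is the fitted change itself because the probe's own signal was used on every array. At 24 h neither tgfb1a probe passed, with changes of -0.20 (adjusted p = 0.458) and -0.73 (SE 0.32, adjusted p = 0.0857), and the second passed under quantile normalization (adjusted p = 0.0455) and capped normexp (adjusted p = 0.000322).

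At 6 h the largest rises in PCSK7 plus p53 morpholino embryos included several transcription factors of the early embryo. The potassium channel tetramerization gene kctd12b rose 32.7-fold (log2 5.03, SE 0.15, adjusted p = 2.94e-08), and aldh1a2, which makes retinoic acid, rose 31.8-fold (log2 4.99, SE 0.21). The neural progenitor factor sox2 rose 27.9-fold (SE 0.25 on the log2 scale), the segmentation clock gene her1 27.4-fold (SE 0.30) and the collagen chaperone serpinh1b 26.4-fold (SE 0.30). The somite gene mespaa, tbx16l, the galectin lgals1l1, the ventral homeobox gene eve1 and anxa1c rose 21.8-, 15.5-, 15.4-, 14.9- and 12.5-fold. The other probe rose by less for kctd12b (log2 2.94), aldh1a2 (2.27), her1 (3.29) and anxa1c (1.64). Among the largest falls, the interferon-stimulated gene isg15 fell 19.9-fold (log2 -4.32, SE 0.39, adjusted p = 1.04e-05) and the p53 target phlda3 6.18-fold (log2 -2.63, SE 0.30). The others were hist1h2a2 (log2 -3.74), rhd (-2.80), rpz5 (-2.79), ms4a17a.2 (-2.78) and cdk5r1a (-2.60), the last an activator subunit of a neuronal kinase. Probes disagreed for cebpz, where 1 of 3 fell (log2 -3.96) and the highest other gave 0.02, and for pla2g12b, where 1 fell (log2 -3.64, SE 0.58) and 2 rose (up to 3.13).

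**Figure D1:**
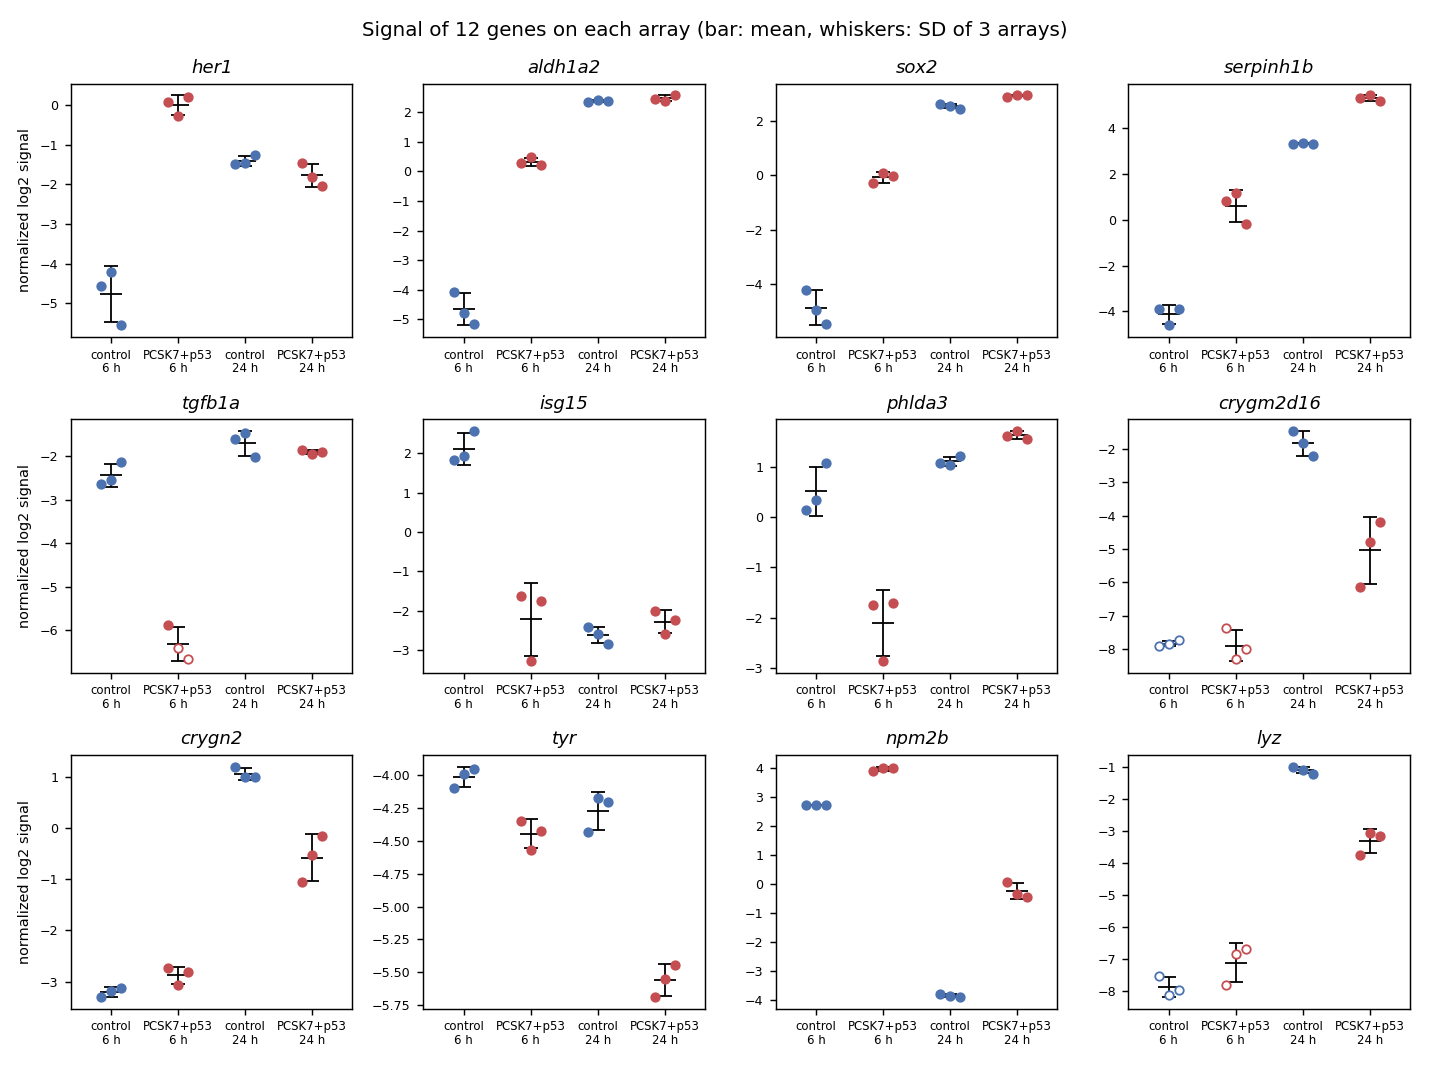
Normalized log2 signal (vertical axis) of 12 genes on each of the 12 arrays by group, with the mean and SD of 3 arrays. Open points were not well above background, and her1, aldh1a2 and sox2 were low in control embryos at 6 h, while crygm2d16, crygn2, tyr and lyz were lower in morpholino embryos at 24 h, with log2 changes of -3.21, -1.64, -1.29 and -2.21.

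Being above background depends on how bright an array is, and the 6 h morpholino arrays were brighter than the 6 h control arrays (75th percentile 630 to 726 against 401 to 509). The numbers of genes measured in only 1 group move with this. In all, 263 genes with a call were well above background on all 3 morpholino arrays and on 0 control arrays. They were led by lgals3b (at least 20.7-fold), spon1b (17.9), ero1a (17.4), prdm1a (15.2), a transcription factor of the hatching gland and fin, and mhc1uba (11.7). All of these are lower bounds on the main values. Under capped normexp, whose offset of 50 shrinks changes of dim genes, lgals3b, spon1b and ero1a changed by 1.83, 1.43 and 1.34 on the log2 scale. In the other direction there were 23 genes with a call, led by ggact.2 (at least 12.9-fold), islr2 (10.9), scn4aa (4.35), tnfsf10l3 (4.05) and sycn.2 (3.68).

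Proprotein convertases were lower at 6 h, where 6 of 7 measured members fell, 0 rose and 1 was not passed (median log2 -0.61, camera adjusted p = 0.0408), with the same counts adjusted over the list alone. The p was 0.328 with an estimated correlation. Its member furinb, a furin paralog, fell by 1.70 (SE 0.11, on 1 of 2 probes) and pcsk5b by 0.74 (SE 0.10). This call was lost under quantile normalization (adjusted p = 0.177), cyclic loess (0.0534) and without control 6 h replicate 2 (0.0574) or morpholino 6 h replicate 1 (0.0726), and the adjusted p ranged from 7.77e-07 to 0.328 over its alternatives. Only 4 of the 7 were well above background on all arrays of a group at 6 h, and all 4 of these fell, too few for the test. At 24 h 4 convertases fell, 0 rose and 3 did not pass (adjusted p = 0.091), and furinb fell by 1.37 on 1 of 2 probes.

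Hox genes, which pattern the body axis, were lower at 6 h, but most of them were near background then. Of the 13 that were well above background on all arrays of a group, 8 fell and 1 rose (median log2 -0.81, adjusted p = 0.0402 when the lists hold only such genes). Over all 45 measured members 28 had a call lower, 2 higher and 15 did not pass, with the same counts adjusted over the list alone (median log2 -0.59, camera adjusted p = 0.000183, from 1.65e-09 to 0.153 over its alternatives). The p was 0.153 with an estimated correlation. The other 20 of these lower calls, on genes not above background throughout either group, are no measure of expression, because genes above background on no array at 6 h had a median change of -0.53 (1222 genes, 600 with a call lower and 57 higher). The gene hoxb8a fell by 2.12 (SE 0.19) and hoxb2a by 1.11 (SE 0.11), while hoxb7a, above background in control embryos alone, was at least 2.73-fold lower. At 24 h 5 Hox genes rose and 2 fell (adjusted p = 0.388).

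Epidermis and enveloping layer genes, which mark the embryo's outer covering, moved in opposite directions at the 2 times. At 6 h 22 of 36 rose, 9 fell and 5 did not pass, with the same counts adjusted over the list alone (median log2 0.46, adjusted p = 0.0242), and of the 31 well above background on all arrays of a group 21 rose and 6 fell. The p was 0.619 with an estimated correlation. The genes icn2 and icn rose 6.96-fold and 6.48-fold (SE 0.11 and 0.12 on the log2 scale), and agr1 was at least 9.85-fold higher. At 24 h 22 fell, 1 rose and 13 did not pass (27 and 1 adjusted over the list alone, median log2 -0.42, adjusted p = 0.0011). The p was 0.653 with an estimated correlation and 0.0577 under quantile normalization (from 6.99e-08 to 0.653 over its alternatives). The protease gene capn12 fell by 1.38 (SE 0.13), anxa1b by 1.06 (SE 0.13), the keratin krt4 by 0.70 on 6 of 9 probes and the basal epidermal factor tp63 by 0.47.

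Ribosomal protein genes also moved in opposite directions. At 6 h 43 of 64 rose, 1 fell and 20 did not pass (44 rose and 1 fell adjusted over the list alone, median log2 0.29, camera adjusted p = 6.82e-05). The p was 0.675 with an estimated correlation. Among them rpl5a rose by 0.72 (SE 0.05) and rplp1 by 0.61 (SE 0.06), while rps27a fell by 0.57. At 24 h 60 fell, 1 rose and 3 did not pass (median log2 -0.42, adjusted p = 2.15e-13), the same counts adjusted over the list alone, with rps9 at -0.99 and rps3 at -0.62. The p was 0.653 with an estimated correlation. Under quantile normalization 8 rose and 8 fell at 24 h (median -0.02, adjusted p = 0.896), and cyclic loess gave 28 lower. The adjusted p ranged from 1.29e-16 to 0.896 over its alternatives.

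Of the patterning lists at 6 h, 14 of 23 Nodal and mesendoderm genes rose and 4 fell (15 and 5 adjusted over the list alone, adjusted p = 0.0588), 13 of 26 BMP and dorsoventral genes rose and 4 fell (adjusted p = 0.21), and 17 of 38 Wnt, FGF, hedgehog and retinoic acid genes rose and 12 fell (adjusted p = 0.323). The Wnt target sp5l rose by 3.54 (SE 0.11, 4 of 4 probes), and the BMP-regulated genes msx1b, id3 and bmp4 rose by 1.83, 1.77 and 1.68. Of 25 neural progenitor genes 14 rose and 6 fell (14 and 7 adjusted over the list alone, adjusted p = 0.0741), with the Notch ligand dlb at 3.41 (SE 0.10) and the hairy-related repressors her3 at 2.94 and her9 at 2.51. Of 50 somite and skeletal muscle genes 20 rose and 12 fell (adjusted p = 0.323), with her7 at 3.37 and msgn1, a presomitic mesoderm factor, at 2.67, and ripply1 was at least 4.82-fold higher. Of 29 notochord and floor plate genes 15 rose and 8 fell (16 and 9 adjusted over the list alone, adjusted p = 0.181).

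In the p53 pathway 15 of 24 genes fell at 6 h, 6 rose and 3 did not pass (15 and 7 adjusted over the list alone, adjusted p = 0.0741). The damage-response genes gadd45aa and gadd45ab fell by 2.42 (SE 0.20) and 1.70 (SE 0.16) and the death gene bbc3 by 2.16 (SE 0.23). At 24 h 5 rose and 2 fell (adjusted p = 0.431). Of 25 apoptosis genes 11 rose and 3 fell at 6 h (adjusted p = 0.17), and at 24 h 7 rose and 6 fell (adjusted p = 0.912), where casp9 fell by 1.12. Of 24 interferon and innate immunity genes 10 rose and 6 fell at 6 h (adjusted p = 0.614), where b2m, the light chain of class I molecules, rose by 1.59 (SE 0.11). At 24 h 7 rose and 5 fell (adjusted p = 0.471), and b2m rose by 1.05.

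The TGF-beta pathway list had 10 of 24 genes lower and 3 higher at 6 h (adjusted p = 0.19) and 9 lower and 0 higher at 24 h (7 and 0 adjusted over the list alone, adjusted p = 0.157). Of the TGF-beta responsive genes 6 of 20 rose and 6 fell at 6 h (median -0.09, mean 0.32, adjusted p = 0.941), with acta2, smooth muscle actin, up by 2.19 (SE 0.11), and at 24 h 6 rose and 4 fell (adjusted p = 0.471), with acta2 up by 1.21.

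The remaining lists at 6 h did not pass. Maternal transcripts had 8 higher and 7 lower of 23 (adjusted p = 0.873), neurons 8 and 14 of 34 (0.369), brain regions 13 and 11 of 33 (0.828), eye 5 and 11 of 24 (0.377), and lens 1 and 9 of 17 (0.0741). Inner ear had 8 higher and 9 lower of 28 (0.873), heart 5 and 6 of 19 (0.873), blood 16 and 6 of 29 (0.21), endothelium 2 and 13 of 28 (0.0741), and extracellular matrix and proteases 14 and 12 of 38 (0.706). Hatching gland had 5 higher and 3 lower of 11 (0.59), neural crest and pigment 4 and 14 of 29 (0.21), endoderm and liver 10 and 5 of 25 (0.623), and yolk lipid transport 9 and 6 of 21 (0.444). Cell cycle had 15 higher and 12 lower of 42 (0.821), ER stress and chaperones 9 and 11 of 30 (0.598), heat shock proteins 13 and 2 of 20 (0.0588), circadian clock 3 and 8 of 19 (0.445), and mitochondrial respiration 13 and 13 of 40 (0.941). Counts adjusted over the list alone were 13 and 12 for brain regions, 10 and 7 for yolk lipid transport, 16 and 13 for cell cycle and 14 and 13 for mitochondrial respiration, and the same for the others. Part of the lower counts came from genes near background. Among genes well above background on all arrays of a group at 6 h, endothelium had 2 higher and 5 lower of 14, eye 5 and 4 of 14, lens 1 and 4 of 9, neural crest and pigment 4 and 8 of 18, neurons 7 and 10 of 23, brain regions 11 and 6 of 22 and inner ear 8 and 5 of 21. On the same terms somites and skeletal muscle had 19 higher and 5 lower of 37, blood 13 and 1 of 17, heart 5 and 2 of 9 and extracellular matrix and proteases 12 and 7 of 30.

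The sign of a list's median was not stable for several lists without a call at 6 h. It turned in at least 1 of 6 scalings for TGF-beta responsive genes, interferon and innate immunity, brain regions, inner ear, somites and skeletal muscle, heart, blood, notochord and floor plate, extracellular matrix and proteases, hatching gland, endoderm and liver, yolk lipid transport, cell cycle and mitochondrial respiration. At 24 h it turned for TGF-beta responsive genes, BMP and dorsoventral genes, interferon and innate immunity, somites and skeletal muscle, endothelium, hatching gland and circadian clock. Median, mean and camera direction differed in sign at 6 h for TGF-beta responsive genes, maternal transcripts, inner ear, heart and mitochondrial respiration, and at 24 h for TGF-beta responsive genes, apoptosis, inner ear, somites and skeletal muscle, endothelium and circadian clock.

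In blood, cahz, an erythroid carbonic anhydrase, rose by 3.83 (SE 0.29, above background on 1 of 3 control arrays, at least 10.1-fold), and among yolk lipid carriers apoa1a rose by 2.56 and fabp1b.1 by 2.97 (above background on 2 of 3 control arrays).

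**Figure D2:**
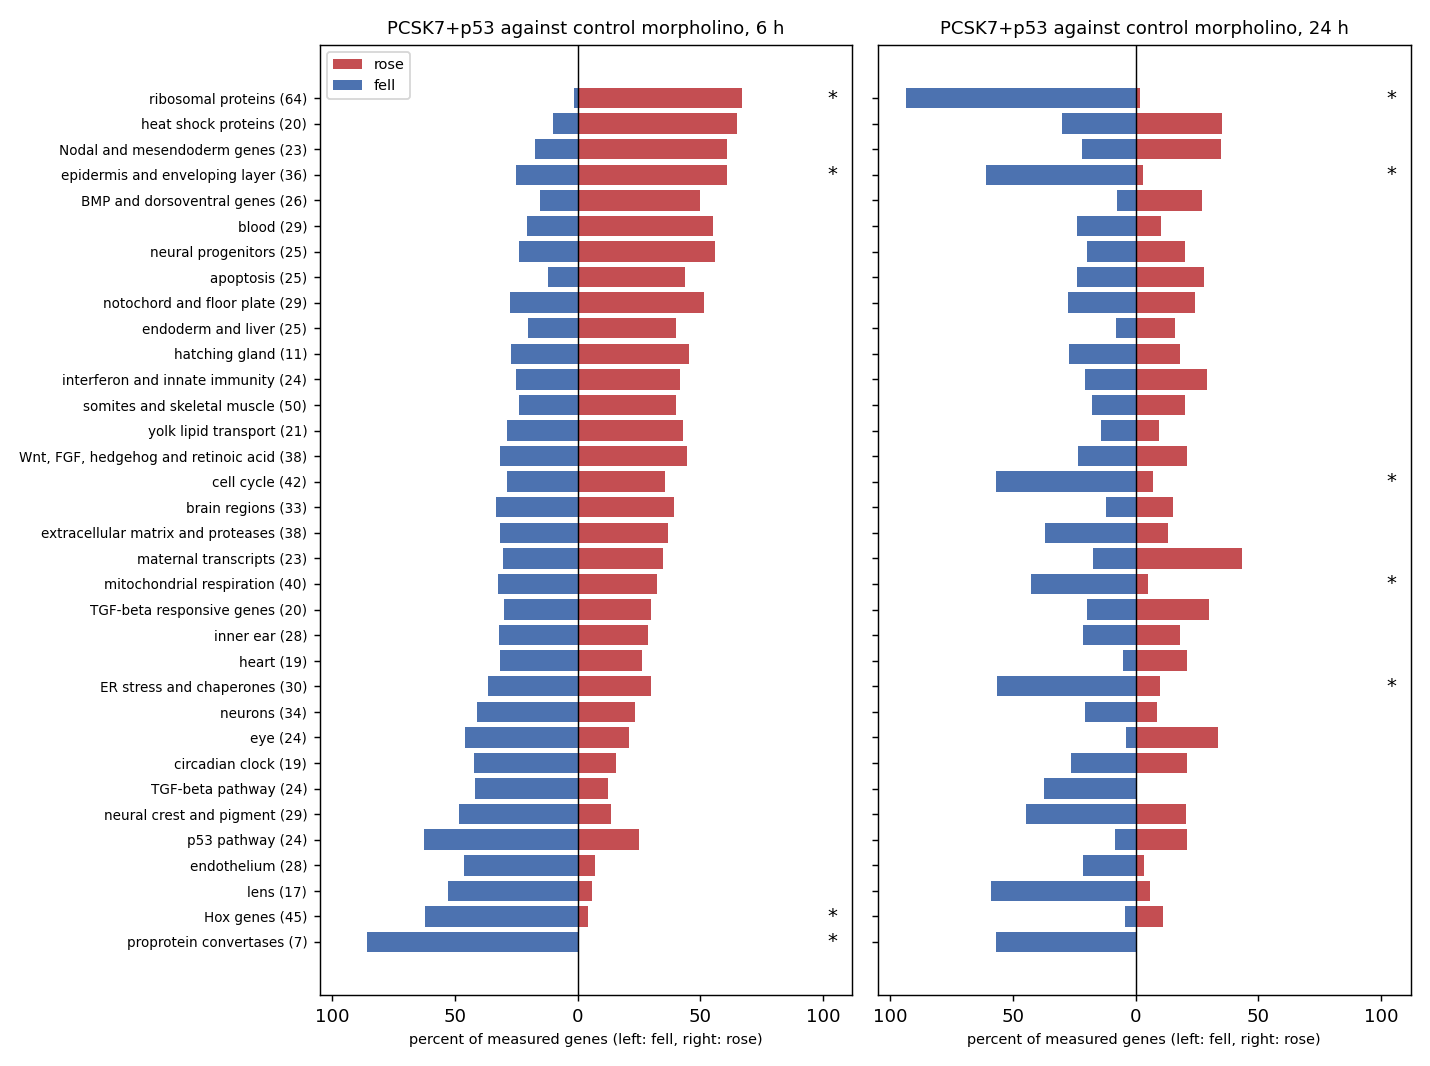
Percent of measured genes that rose (right) and fell (left) in each of the 34 gene lists at 6 h and 24 h, with the number measured in brackets and an asterisk where camera's adjusted p was under 0.05. Ribosomal protein and epidermal genes lie to the right at 6 h and to the left at 24 h, and 0 of the 34 lists passed with an estimated correlation.

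At 6 h 21885 of 36686 probes (59.7%) were called, 10426 higher and 11459 lower, and 4976 changed at least 2-fold. At the level of genes 4105 had a call higher and 3980 lower, 993 and 740 of them at least 2-fold. Probes well above background on all arrays of a group held 19000 of the calls, 9933 higher and 9067 lower. Of the calls on probes above background on no array 2108 of 2297 were lower, which the background level rather than expression can give. The median over all probes was -0.04. Capped normexp moved that median to -0.27 and left 1347 calls of at least 2-fold. Of its calls 26.7% were higher, against 47.6%.

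At 24 h the largest falls among genes above background on all 6 arrays were crystallins. Among the rises, npm2b, an egg chromatin gene, rose 12.2-fold (log2 3.61, SE 0.12, adjusted p = 1.14e-07) and mala.1 8.76-fold (log2 3.13, SE 0.13). They were followed by alox5b.3 (5.66-fold), rsrp1 (5.64-fold), ankar (4.44-fold), gfi1aa (4.13-fold, log2 2.05, SE 0.53, adjusted p = 0.0104) and serpinh1b (4.01-fold). Probes disagreed for foxred2, where 1 rose by 2.22 and the other fell by 0.87, and for ccdc137, where 1 rose by 2.08 and the other fell by 1.31. All 10 of the largest falls were gamma-M crystallins, structural proteins of the fish lens, from crygm2d16 (9.27-fold, log2 -3.21, SE 0.43, adjusted p = 0.000245) through crygmxl2 (-3.13), crygm2d15 (-3.08), crygm2d3 (-3.05), crygm2d17 (-3.03), crygm2d12 (-3.03), crygm2d4 (-2.98), crygm2d20 (-2.98) and crygm2d9 (-2.96) to crygm2d14 (-2.93). These paralogs are nearly identical in sequence, so which of them a probe reads is uncertain.

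The bound in 1 group alone at 24 h gave, among genes with a call, 16 above background in control embryos only and 66 in morpholino embryos only. These numbers move with brightness too (75th percentile 1014 to 1080 in morpholino and 692 to 984 in control embryos). The former were led by ggact.2 (at least 94.3-fold), ggact.3 (11.6), crygm2c (7.45), crygm2b (5.95) and acsm3 (5.03), and the latter by fgf23 (6.86), macrod1 (6.23), mhc1uba (6.18), alox5b.2 (5.73) and neurod2 (5.52). Under capped normexp the fitted changes were smaller, at -3.32 for ggact.2, -1.32 for ggact.3, -0.87 for crygm2c, 0.58 for fgf23 and 0.74 for neurod2.

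Beyond the gamma-M genes, 10 of 17 measured lens genes fell at 24 h and 1 rose (10 and 2 adjusted over the list alone, median log2 -0.68, adjusted p = 0.152). The gene crygn2 fell by 1.64 (SE 0.19), cryba1b by 1.48 (SE 0.21) and cryba4 by 1.28 (SE 0.18), all structural lens proteins. Of 29 neural crest and pigment genes 13 fell and 6 rose (13 and 8 adjusted over the list alone, adjusted p = 0.431), where the melanin-forming genes slc24a5, tyr, tyrp1b and pmela fell by 1.30 (SE 0.09), 1.29 (SE 0.10), 1.35 (SE 0.17) and 1.01 (1 of 2 probes). The tyr signal in control embryos was no higher at 24 h (-4.437 to -4.175) than at 6 h (-4.098 to -3.952). The difference between times was smaller than the 24 h change for tyr (-0.85) and slc24a5 (-0.78), so part of their lower signal was already present at 6 h. For pmela it was larger (-1.92). Where the signal was lower at both times, an offset of the probe or session cannot be told apart from a change in expression.

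Cell cycle genes fell at 24 h, 24 of 42 lower and 3 higher (25 and 3 adjusted over the list alone, median log2 -0.25, camera adjusted p = 0.0111). The p was 0.653 with an estimated correlation, 0.0577 under quantile normalization, 0.132 under cyclic loess and 0.072 under capped normexp (from 8e-05 to 0.653 over its alternatives). The replication genes gmnn and mcm7 fell by 0.82 (SE 0.06) and 0.68 (SE 0.07, 3 of 4 probes). The cyclin ccna2 fell by 0.47 (2 of 3 probes). Of 30 ER stress and chaperone genes 17 fell and 3 rose, with the same counts adjusted over the list alone (median log2 -0.31, adjusted p = 0.0135). The p was 0.564 with an estimated correlation, 0.0531 under quantile normalization and 0.072 under capped normexp (from 1.62e-05 to 0.564 over its alternatives). The secretory chaperone hsp90b1 fell by 1.11 (SE 0.15), chac1 by 0.66, manf by 0.59 and hyou1 by 0.82 on 1 of 3 probes. Of 40 mitochondrial respiration genes 17 fell and 2 rose, with the same counts adjusted over the list alone (median log2 -0.16, adjusted p = 0.023). The p was 0.745 with an estimated correlation, 0.66 under quantile normalization, 0.424 under cyclic loess, 0.0978 under capped normexp and 0.0585 without control 24 h replicate 1 (from 0.00038 to 0.745 over its alternatives). The adenine nucleotide carrier slc25a4 fell 5.12-fold (log2 -2.36, SE 0.16) and the complex III subunit uqcrc1 by 1.18 (SE 0.07).

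Lists that did not pass at 24 h included Nodal and mesendoderm genes (8 higher and 5 lower of 23, adjusted p = 0.471), BMP and dorsoventral genes (7 and 2 of 26, 0.229), neural progenitors (5 and 5 of 25, 0.769), neurons (3 and 7 of 34, 0.648) and brain regions (5 and 4 of 33, 0.858). Eye had 8 higher and 1 lower of 24 (6 and 0 adjusted over the list alone, 0.0984), inner ear 5 and 6 of 28 (0.858), somites and skeletal muscle 10 and 9 of 50 (0.881), heart 4 and 1 of 19 (0.157), endothelium 1 and 6 of 28 (0.936) and notochord and floor plate 7 and 8 of 29 (0.858). Extracellular matrix and proteases had 5 and 14 of 38 (0.431), hatching gland 2 and 3 of 11 (0.912), endoderm and liver 4 and 2 of 25 (0.431), yolk lipid transport 2 and 3 of 21 (0.769) and Wnt, FGF, hedgehog and retinoic acid genes 8 and 9 of 38 (0.912). Among these lists the counts adjusted over the list alone differed for neurons (2 and 6), brain regions (4 and 4), somites and skeletal muscle (10 and 8), extracellular matrix and proteases (6 and 14), hatching gland (2 and 4), endoderm and liver (4 and 1) and yolk lipid transport (2 and 1).

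At 24 h 16775 of 36686 probes (45.7%) were called, 7550 higher and 9225 lower, with 2479 changed at least 2-fold. At the level of genes 2695 rose and 3319 fell, 324 and 425 of them at least 2-fold, and 16234 of the calls were on probes well above background on all arrays of a group. The median over all probes was -0.04, and -0.11 under capped normexp, where 37.1% of calls were higher, against 45.0%, and 702 calls were of at least 2-fold.

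The change between morpholino and control embryos differed between the times for many genes. The 6 h and 24 h arrays of morpholino embryos lay on different slides, so a shift between those slides would enter this difference. Among genes well above background on all 12 arrays, the largest differences, 24 h minus 6 h, were negative for her1 (-5.14, SE 0.42, adjusted p = 1.55e-05), aldh1a2 (-4.90, SE 0.30), kctd12b (-4.71, SE 0.22), sox2 (-4.43, SE 0.36) and the transglutaminase tgm2b (-4.06, SE 1.28, adjusted p = 0.0254). They were positive for isg15 (4.65, SE 0.55), cebpz (3.72, SE 0.34, of whose 3 probes only 1 fell at 6 h), pla2g12b (3.27, SE 0.82, 1 of 3 probes), rpz5 (3.25, SE 0.44) and phlda3 (3.14, SE 0.43). By list, ribosomal protein genes differed with 61 of 64 lower and 0 higher (62 lower adjusted over the list alone, median -0.73, adjusted p = 4.53e-15), and the p was 0.547 with an estimated correlation. Epidermal genes differed with 24 of 36 lower and 3 higher, the same adjusted over the list alone (median -0.77, adjusted p = 4.58e-05), and Hox genes with 19 of 45 higher and 4 lower (21 and 4 adjusted over the list alone, median 0.82, adjusted p = 9.47e-05). With an estimated correlation the p was 0.547 for epidermal and 0.143 for Hox genes. Only 11 Hox genes were well above background on all 12 arrays, 5 with a difference higher and 2 lower (median 0.86), so the larger count also holds the background offset at 6 h. The p53 pathway differed with 13 of 24 higher and 3 lower (16 and 4 adjusted over the list alone, median 0.48, adjusted p = 0.0142), and the p was 0.547 with an estimated correlation. In all, 17036 probes (46.4%) had a called difference, 8057 higher and 8979 lower, with 5518 at least 2-fold. Capped normexp moved the median of all probes from -0.01 to 0.14 and the share of calls that were higher from 47.3% to 61.9%, with 1663 calls of at least 2-fold.

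**Figure D3:**
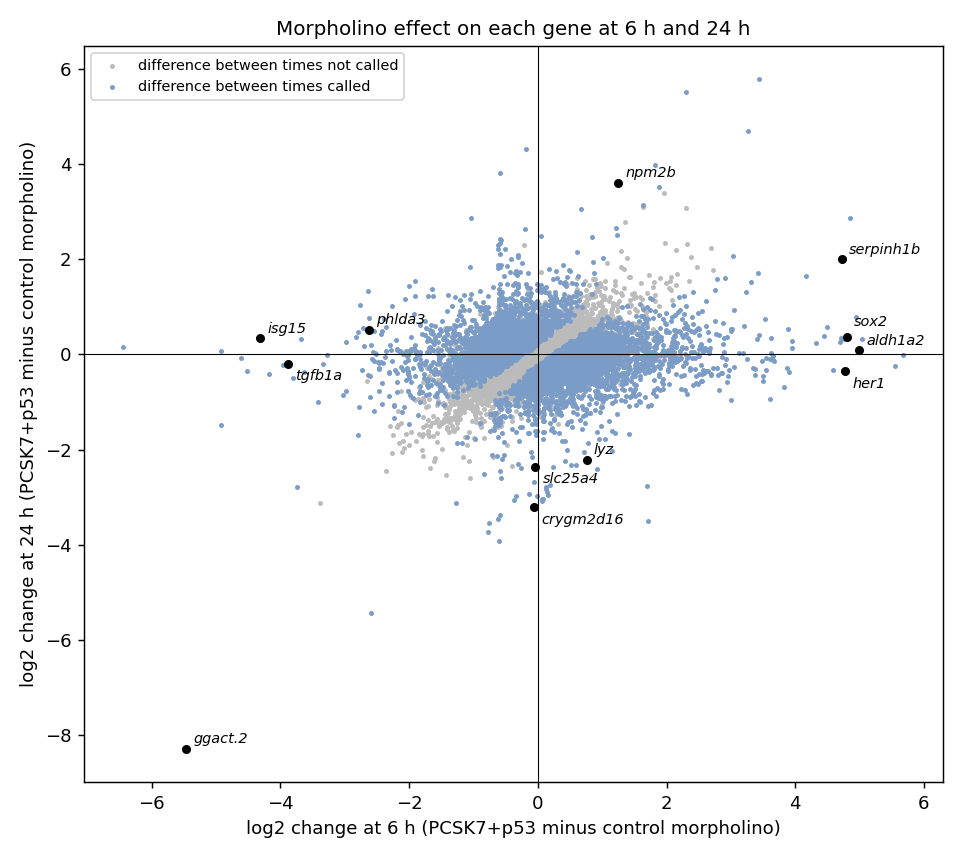
Log2 change at 6 h (horizontal axis) against that at 24 h (vertical axis), PCSK7 plus p53 minus control morpholino, for each of 12849 genes, blue where the difference between times was called. The values of her1, aldh1a2 and sox2 lie far to the right and near 0 on the vertical axis, and ggact.2, at the lower left, was not above background in morpholino embryos, so its position only follows the measured signal.

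As background, development itself changed most of the transcriptome. In control embryos the embryonic globin hbbe3 (log2 13.20), the muscle light chain myl10 (12.89), aldoab (12.62), apoa1a (12.57) and hbae1.1 (11.91) rose most from 6 h to 24 h. The pluripotency factor nanog (-10.12), the maternal linker histone h1m (-9.91), cth1 (-9.68), ccnp (-9.50) and cldnd (-9.47) fell most. With slide as a block the changes were the same, with SE from 0.08 to 0.15 and adjusted p of at most 8.65e-06. Within slides 1, 2 and 3 hbbe3 changed by 13.32, 12.99 and 13.30 and nanog by -10.28, -10.05 and -10.02, and 99.9, 99.9 and 99.8% of called probes moved the same way as in the fit. In control embryos 33048 probes (90.1%) were called, 16702 higher and 16346 lower, and 24398 changed at least 2-fold. In morpholino embryos myl10 (13.42), hbbe3 (12.47), aldoab (12.36), pvalb9 (11.91) and apobb.1 (11.43) rose most and nnr (-10.87), h1m (-10.12), wee2 (-9.99), cth1 (-9.96) and cldnd (-9.26) fell most. There 32936 probes (89.8%) were called, 16567 higher and 16369 lower, and 23993 changed at least 2-fold, but each time lay on its own slide, so slide and time cannot be told apart. The median of all probes depended on the scaling in both, at 0.04 and 0.01 here, -0.30 and -0.28 with median scaling, -0.28 and -0.24 with quantile normalization, 0.18 and 0.19 with the 75th percentile over detected probes, and -0.41 and -0.23 with capped normexp. In control embryos 36.8% of calls were higher under capped normexp, against 50.5%.

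On the scale from control embryos at 6 h (0) to control embryos at 24 h (1), over 4994 genes for the morpholino arrays and 4991 to 5007 for the control arrays, morpholino embryos at 6 h lay at 0.0581 ± 0.001 (SD, n = 3) and control embryos at 0.0024 ± 0.0124 (exact permutation p = 0.1). At 24 h morpholino embryos lay at 0.982 ± 0.004 and control embryos at 0.998 ± 0.0049 (SD, n = 3, exact permutation p = 0.1). The smallest p possible with 3 against 3 arrays is 0.1, so neither difference could pass. The position at 24 h was 0.970 from rising genes and 1.01 from falling genes.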

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

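The tests of developmental stage at 6 h, of a shift of each probe common to all arrays of session 2, of a lag at 24 h, of cross-hybridisation and of different parents were chosen after the result was seen. The results here are those whose morpholino effect differed between 24 h and 6 h by a test of the difference itself, in limma, and values are 24 h minus 6 h on the log2 scale. In all, 17036 probes had a called difference, which also holds any shift between the slides of morpholino embryos at 6 h and at 24 h. Of 100 drawn splits of the samples, 1, the real one, gave as many, and the highest other gave 10932, so a share under 0.05 was reached. That split structure follows the samples, since splits with the true groups at 6 h alone gave 7390 to 10932 calls (9 splits), those with the true groups at 24 h alone 1523 to 3593 (9 splits) and those mixed at both times 0 to 1 (81 splits). The split with the true groups and 1 time mirrored was drawn 0 times, so its count is not known. Mixed splits put the group differences into the spread, which lowers their counts, so the share is no fair measure of chance.

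Gene lists with a difference were the p53 pathway (0.483), epidermis and enveloping layer (-0.769), Hox genes (0.816) and ribosomal proteins (-0.725), as medians. With an estimated correlation none kept its call, with adjusted p = 0.547, 0.547, 0.143 and 0.547.

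Among genes with the largest rises at 6 h the differences were kctd12b -4.71, aldh1a2 -4.90, sox2 -4.43, her1 -5.14, serpinh1b -2.72, mespaa -4.06, tbx16l -3.67, lgals1l1 -3.81, eve1 -3.37 and anxa1c -3.68. Among the largest falls they were isg15 4.65, cebpz 3.72 (probes disagreed at 6 h), hist1h2a2 0.95, pla2g12b 3.27 (probes disagreed at 6 h), rhd 1.098, rpz5 3.25, ms4a17a.2 1.67, phlda3 3.14 and cdk5r1a 2.80. At 24 h cdk5r1a was above background on 0 arrays, so its difference rests on the 6 h change, and hist1h2a2 was above background there on 2 of 3 control and 0 morpholino arrays.

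Among the largest rises at 24 h the differences were npm2b 2.36, mala.1 1.504, alox5b.3 1.28, rsrp1 2.45, foxred2 2.74 (probes disagreed at 24 h), ankar 1.54, ccdc137 -0.96 (probes disagreed at 24 h) and gfi1aa 2.36. Among the gamma-M crystallins they were crygm2d16 -3.15, crygmxl2 -1.86, crygm2d15 -3.14, crygm2d3 -2.68, crygm2d17 -3.11, crygm2d12 -3.09, crygm2d4 -2.64, crygm2d20 -2.96, crygm2d9 -3.12 and crygm2d14 -2.80. Of these crygm2d16, crygm2d15, crygm2d17, crygm2d12, crygm2d4, crygm2d20 and crygm2d9 were above background on 0 arrays at 6 h, so their differences rest on the 24 h change, as does that of gfi1aa (1 control array and 0 morpholino arrays at 6 h).

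Among signalling and patterning genes the differences were tgfb1a 2.38 and 3.68 on its probes, tgm2b -4.06, pcsk5b 0.58, acta2 -0.98, msx1b -1.95, id3 -1.93, bmp4 -1.50, dlb -3.09, her9 -1.99, her3 -2.57, her7 -3.67, msgn1 -2.36, sp5l -3.62, hoxb8a 2.17, hoxb2a 1.04 and nanog 0.90. Among stress and immune genes they were gadd45aa 2.92, gadd45ab 1.83, bbc3 2.23, b2m -0.53, chac1 -0.40, manf -0.50, dnajb1b 1.48, dnajb1a 0.69, hspa8 -0.43, lyz -2.97 and ikzf1 1.85. In blood, yolk and outer layers they were cahz -4.52, apoa1a -2.96, fabp1b.1 -3.30, icn2 -3.24, icn -3.13, tp63 -0.33, capn12 -0.70, anxa1b -2.58 and krt4 -1.33. In lens and pigment they were crygn2 -1.97, cryba1b -0.84, pmela -1.92, slc24a5 -0.78, tyr -0.85 and tyrp1b -0.74. The others were rpl5a -0.84, rplp1 -0.90, rps9 -0.94, rps3 -0.74, mcm7 -0.75, ccna2 -0.72, zp3b 0.90, per1a -0.70, per2 1.21, uqcrc1 -0.73 and slc25a4 -2.32. The genes lyz, ikzf1, cryba1b and tyrp1b were above background on 0 arrays at 6 h, so their differences rest on the 24 h change. The differences of tgfb1a (1 of 3 morpholino arrays above background at 6 h on each probe), cahz (1 of 3 control arrays) and fabp1b.1 (2 of 3 control arrays) rest in part on signal at background.

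The first pattern is the set of 1733 genes changed at least 2-fold at 6 h. A signal-dependent response of the scan sessions is argued against as the whole cause, because 85.3% of these genes stayed called and at least 2-fold changed under quantile normalization and 94.5% under cyclic loess, and so is a shift of each probe common to all arrays of session 2 for the 1042 of them above background on all 12 arrays, because their 24 h change in the same direction was 18.4% of the 6 h size. A later stage of the 6 h morpholino pools stays open as part of the cause. Among all genes above background at 6 h, those that fall at least 4-fold by 24 h in controls had a median of -0.174 at 6 h (1705 genes). Those that rise at least 4-fold had 0.353 (1557 genes). These sets hold genes of any 6 h change, so the medians do not show how far the 1733 genes follow stage. Of the 1733 genes 126 were above background on no array at 6 h, where the background level alone could give the call. No time point near 6 h separates a stage difference from a morpholino effect, and slide and session cannot be told apart from it.

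The second pattern is the lower calls among lens and pigment genes at 24 h, although neither list passed in camera (adjusted p = 0.152 for lens and 0.431 for neural crest and pigment). A lag in proportion to each gene's developmental change stays open for both lists. The lens median of -0.682 lay below all 10000 matched random lists (lowest -0.623), so lens genes fell more than separately drawn genes of like developmental change. Those lists drew their genes independently, while genes of 1 tissue can move together, so their spread can be too narrow to decide. The neural crest and pigment median of -0.276 lay at the 1.11 percentile, which 1 of 34 lists can reach by chance. Cross-hybridisation among gamma-M crystallin probes stays open for that family, and the 17 measured lens genes with the median of -0.682 hold none of its members. A lag of late-starting genes alone stays open, as do slide and session. A morpholino effect on lens and pigment is therefore only a possible explanation. Part of the lower signal of tyr and slc24a5 was already present at 6 h, with differences between times of -0.85 and -0.78, which an offset of the probe or session can give too.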

How the results depend on the processing

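The capped normexp, cyclic loess and the filter on the compared groups were chosen after seeing the data. The 106 named gene values were checked under both normexp versions, median and quantile scaling, cyclic loess, the replicate and random slide blocks, and without each replicate. The other alternatives were not run for these values. Apart from the planned normexp, 2 values had another call, which were 1 tgfb1a probe at 24 h and ddx4 at 24 h (lost under capped normexp). Of 25 genes named by a bound, 25 kept their direction and call under each scaling but capped normexp (23), where psmb8a turned to -0.22 and sox32 lost its call. Signal over background limits the calls on dim genes, and 2297 calls at 6 h were on probes above background on no array.

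Planned normexp left 36 calls at 6 h (36 at least 2-fold), 0 at 24 h (0) and 0 for the difference (0) in limma, against 3503, 720 and 1479 probes at unadjusted p under 0.05, and 27210, 16730 and 16662 calls with the capped version. Over time it gave 8947 calls (8401 at least 2-fold) in control and 11188 (10491) in morpholino embryos. It weakened 97 of the named gene values and reversed 4, to -0.17 for cahz, -0.10 for apoa1a and 0.013 for rps27a at 6 h and to 0.0072 for tgfb1a on 1 probe at 24 h. A few spots with very high local background upset its fit, as the capped version shows. Capped normexp gave 1347, 702 and 1663 calls of at least 2-fold at 6 h, at 24 h and for the difference. Its offset shrinks the changes of dim genes, which lowers such counts. How far the offset alone accounts for the lower counts was not tested.

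Probes detected on all 12 arrays gave 2660, 1166 and 2852 calls of at least 2-fold at 6 h, at 24 h and for the difference, and 15635 and 15163 over time in control and morpholino embryos, with fewer probes tested (26470). The authors' table gave 10036 calls (2170 at least 2-fold) at 6 h, 7993 (1091) at 24 h, 8333 (2429) for the difference, and 15568 (11644) and 15434 (11323) over time. Fewer probes tested (17127) account for this, since the main values of those probes gave 10632 (2469), 7905 (1157), 8397 (2698), 15551 (11490) and 15494 (11276).

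Gene lists passing numbered 4 at 6 h, 5 at 24 h and 4 for the difference. With an estimated correlation camera passed 0, 0 and 0, against 3, 1 and 2 at unadjusted p under 0.05. Planned normexp gave 21 at 6 h and 21 for the difference, capped normexp 15, 3 and 9, and fry with slide as a random block, which tests each list on its own, 27, 20 and 26. At 24 h quantile normalization passed 0 in camera (8 at unadjusted p under 0.05) and cyclic loess 3, and the cause was not tested. Over the alternatives the adjusted p ranged at 6 h from 4.44e-06 to 0.619 for epidermis and from 2.46e-16 to 0.675 for ribosomal proteins. For the difference it ranged from 0.00116 to 0.547 for the p53 pathway, 1.39e-09 to 0.547 for epidermis, 1.39e-09 to 0.143 for Hox genes and 1.24e-28 to 0.547 for ribosomal proteins.

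Leaving out each replicate gave 20165 to 21278 calls at 6 h, 13990 to 15195 at 24 h, 15471 to 16629 for the difference, and 32464 to 32644 and 32338 to 32593 over time. Lists passing ranged from 3 (without control 6 h replicate 2) to 9 (without control 6 h replicate 1) at 6 h, from 4 to 6 at 24 h, and stayed at 4 for the difference. The stage position at 24 h was 0.980 to 0.984 on leaving out each replicate, 0.990 with quantile normalization, 0.999 with genes changed at least 2-fold and 0.988 as a median.

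With the replicate number as a block (replicate block) there were 21171, 15719 and 16033 calls at 6 h, at 24 h and for the difference, 32888 and 32740 over time, and 4, 5 and 4 lists passing. Same-numbered arrays correlated at -0.053 to 0.016, so the numbers do not pair the samples by this check, although in control embryos a number is also a slide (0.016, 0.013 and 0.011 between the times). Slide as a random block had a consensus correlation of -0.117 and, like the replicate block, changed the call of 0 of the 106 named gene values in limma. All arrays of a morpholino group lay on the same slide. The block therefore cannot remove a slide effect from the comparisons of morpholinos, and the unchanged calls say nothing about it.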

Other observations

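The tests of different parents and of another probe of the same genes were chosen after the result was seen. Heat shock genes split at 24 h, where the HSP40 co-chaperones dnajb1b and dnajb1a rose by 1.87 (SE 0.06) and 1.19 (SE 0.12) while the constitutive chaperone hspa8 fell by 0.57 on 11 of 11 probes. In that list 7 of 20 rose and 6 fell (8 and 6 adjusted over the list alone, adjusted p = 0.471). In blood, the neutrophil and macrophage genes lyz and mpx fell by 2.21 (SE 0.29) and 0.67 (SE 0.12) while the lymphoid factor ikzf1 rose by 1.27 (SE 0.11), with 3 of 29 higher and 7 lower (adjusted p = 0.431). In the circadian clock per1a fell by 1.37 and per2 rose by 1.03 on 1 of 2 probes, with 4 of 19 higher and 5 lower (adjusted p = 0.858).

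Several genes known from the egg or early embryo rose at 24 h, picked here after their values were seen. The egg coat gene zp3b rose by 1.18 (SE 0.11, 6 of 6 probes), the pluripotency factor nanog by 0.98 (2 of 3 probes), the germ cell helicase ddx4 by 0.91 (SE 0.09) and the mesendoderm factor mixl1 by 1.58 (SE 0.23, 4 of 4 probes). The endoderm factor sox32 was at least 2.05-fold higher. Under capped normexp ddx4 (0.12, adjusted p = 0.274) and sox32 (0.05, adjusted p = 0.743) had no call. The list of maternal transcripts did not pass, with 10 of 23 higher and 4 lower (adjusted p = 0.113, and 0.745 with an estimated correlation).

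The third pattern is change shared by both times. Of 259 genes changed at least 2-fold at both, 228 moved in the same direction, 89 higher and 139 lower, where independent changes would give 25 and 24.5. A technical difference that belongs to single probes stays open. The 6 h change of 1 probe correlated with the 24 h change of another probe of its gene at 0.092, against 0.285 within the same probe. The mean change over both times correlated at 0.581 between 2 probes of a gene (5557 genes), which a change at 1 time alone gives too. Of the 228 genes 69 had another probe above background on all 12 arrays. It was called in the same direction at both times for 42% of these (95% interval 30.2 to 54.5), against 19.6% of such probes of all genes. That baseline holds genes of any change, called or not, so the comparison cannot decide. Embryos of different parents or spawnings in the scan sessions could also give the shared change, since 0 scan sessions hold arrays of both morpholinos. They cannot be told apart from a morpholino effect, nor can slide and session. 

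For the other counts of calls, the 10 splits of 6 arrays are too few for a share under 0.05. At 6 h the real split gave 21885 calls and the highest other 4, at 24 h 16775 and 1, in control embryos over time 33048 and 0, and in morpholino embryos over time 32936 and 0, and in each 1 split, the real one, gave as many.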
